A study of Mus musculus with 6 samples.

How the data were processed

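Gene expression was measured by RNA sequencing of 6 mouse libraries. They were 1 library of embryonic stem cells (ESC), 1 of mouse embryonic fibroblasts (MEF), 2 of control induced pluripotent stem cell (iPSC) lines, numbered 3 and 7, and 2 of iPSC lines labelled with palmitoylcarnitine (PC iPSC), numbered 5 and 13. Per the labels' protocols, ESC and iPSC were kept with leukemia inhibitory factor on fibroblast feeder cells that had been treated with mitomycin C, MEF were grown in serum medium, total RNA was extracted, and libraries were made with an mRNA kit. Per the labels the ESC library is titled B6, which is also a short name of a mouse strain, and its source name is B6/blu. No label says which strain or cell line these names stand for. The dose and timing of palmitoylcarnitine, the reprogramming method and the strand treatment of the kit are not given in the sources used here.

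The deposited table of the series holds, per the file headers, uniquely assigned read counts per gene and the library total. The counts are whole numbers that sum to that total in each library. The authors also deposited RPKM values, which are read counts scaled by gene length and by the library total. Recomputing count, length and total into RPKM gave the deposited values within a relative difference of 5.1e-15. The per-library tables held the same counts as the series table, with 0 counts differing, and 17 to 28 gene lengths per library that differed between the tables. CASAVA 1.8.2 and the mouse build mm10 are named in the submitters' processing notes, with no role given. The aligner, the counting program, the annotation and the use of strand are not given in the sources used here. Where strand is not used, reads of overlapping antisense genes cannot be told apart, and reads of near-identical gene copies are uncertain. Among genes with 1 to 20 reads, even counts made up 62.4% to 67.5% of values, against 48.8% to 50.6% above 20 reads. An excess of even counts arises where both mates of a pair are counted, so low counts may hold fewer independent fragments than their size, and intervals on them are then too narrow.

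The table held 19330 genes, of which 19279 were placed on chromosomes by gene ID in the RefSeq annotation of GRCm38 (mm10). Of all entries, 41 are named by an accession instead of a symbol, and they hold 0.003% of the reads. They stayed in the table. Library totals ran from 26.51 M to 27.99 M reads. A count of 0 allows up to 3 reads per library, which is 0.107 to 0.113 CPM (counts scaled to library size). Intervals and floors cover counting error only. No pair of libraries agreed within sampling noise, the lowest chi-square per gene being 9.5, between control iPSC 7 and PC iPSC 13.

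Counts were tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood test with TMM scaling, after its default expression filter left 16435 genes. The planned test for RPKM values was limma, and edgeR was the planned test if raw counts were found, as they were. The model had 4 group means over all 6 libraries, so that the 4 iPSC lines gave 2 residual degrees of freedom (prior degrees of freedom 4.75, biological coefficient of variation 0.18). The single ESC and MEF libraries are assumed to vary like the iPSC lines. The labels do not say that lines or libraries came from separate cultures or animals, so p-values measure only the spread between these samples. Adjusted p-values are Benjamini-Hochberg values over all tested genes, with a threshold of 0.05. ESC against MEF, 1 library against 1, was described without a test.

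The 32 gene lists held 853 different genes, of which 835 were in the table, and 31 lists had at least 5 tested members. Some lists shared genes. Lists were tested with limma 3.58.1 by camera at a preset correlation of 0.01, with an estimated correlation beside it, and by fry. Camera compares a list with the other genes, and fry asks only whether the list's genes move one way on balance. The lists, groups, tests and most alternatives, and the rule for naming genes, were fixed before the data were examined. The rule took the 12 higher and 12 lower genes of largest fold change for PC against control iPSC, and 10 in each direction for ESC and MEF. These had to be past the threshold with no overlap of groups. Places left open were filled with genes that had no overlap and an RPKM of at least 1 in the higher lines, and these are given as not past the threshold. Up to 4 members of each list and a fixed set of pluripotency, carnitine, kinase and imprinted genes were added, and genes known only by predicted names were passed over. Genes with no read on one side are given as at least N-fold against a floor of 3 reads per library. Those with 1 to 3 reads have a ratio with its 95% counting interval.

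The tests were tried on simulated counts with 200 changed genes. These were drawn only from genes above a floor of mean iPSC expression, so the rates below do not cover genes of lower expression. For PC against control iPSC, over 15489 genes, 4 of 67 genes changed 2-fold were called, 50 of 67 changed 4-fold and 61 of 66 changed 8-fold, with 5 false calls. For iPSC against ESC, over 15473 genes, the numbers were 0 of 67, 39 of 67 and 56 of 66, with 2 false calls. A simulated list of 79 genes shifted 1.5-fold was called with the preset correlation and not with the estimated one, and 0 other lists were called. Genes were drawn independently there, while estimated correlations in the PC against control data reached 0.78 for fibroblast and 0.80 for interferon genes. The simulation therefore cannot show how often lists of correlated genes are called falsely at the preset correlation.

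The alternatives were a pseudocount of 0.1, no filter, a mean RPKM of at least 5, median-of-ratios scaling, quantile normalization, limma without a trend, DESeq2 1.42.0, a fit of the 4 iPSC libraries alone and leaving out each iPSC line in turn. Limma with a trend and a fit without chromosome 11 were added later. The pseudocount, quantile and limma alternatives used log2(RPKM + pseudocount) with a pseudocount of 1 unless stated, over genes with an RPKM of at least 1 in any library. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.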

Results

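RNA from 4 mouse iPSC lines, 1 ESC library and 1 MEF library was sequenced to compare iPSC associated with palmitoylcarnitine, the acylcarnitine form in which palmitate enters mitochondria, with control iPSC and with ESC. The groups held 2 PC iPSC lines (5 and 13), 2 control iPSC lines (3 and 7), 1 ESC library and 1 MEF library. Assigned reads came to 27.72 M and 27.16 M in PC iPSC 5 and 13, 27.61 M and 26.51 M in control iPSC 3 and 7, 27.93 M in ESC and 27.99 M in MEF. At least 1 read was found for 17463, 17309, 17234, 17347, 17201 and 16326 genes, in the same order. Levels are RPKM, with the SD over 2 lines of a group or over all 4 iPSC lines. Folds are on the log2 scale from edgeR with their standard error (SE). All gene positions are on GRCm38 (mm10) from RefSeq, and the genes located are protein-coding unless stated.

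The pluripotency genes Pou5f1 and Nanog and the carnitine genes Cpt1a and Slc25a20 did not pass the test between PC and control iPSC. Pou5f1, the octamer-binding factor of pluripotent cells (chromosome 17, 35506032 to 35510777), stood at 459 ± 81.9 in PC iPSC and 509 ± 30.8 in control iPSC (SD, n = 2 each), a log2 difference of -0.17 (SE 0.18, adjusted p = 0.963). Nanog, a homeobox factor of the same network (chromosome 6, 122707489 to 122714633), stood at 437 ± 50.4 and 391 ± 4.06, a difference of 0.14 (SE 0.14). Cpt1a, the carnitine palmitoyltransferase of the outer mitochondrial membrane (chromosome 19, 3322326 to 3385735), was at 38.1 ± 0.689 and 38.3 ± 3.54, a difference of -0.03 (SE 0.13). The carnitine-acylcarnitine carrier Slc25a20 (chromosome 9, 108662136 to 108684642) was at 51.0 ± 10.4 and 44.5 ± 3.68, a difference of 0.17 (SE 0.16).

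Across the 16435 genes tested, edgeR called 0 genes between PC and control iPSC, with 385 at an unadjusted p under 0.05, of which 195 were higher and 190 lower. The smallest adjusted p was 0.963. DESeq2 also called 0, with 248 at an unadjusted p under 0.05. The 2 lines of one group lay outside the range of the other for 5170 genes, or 31.5%, where chance gives 33.3%. The other two splits of the 4 lines into pairs called 0 genes each by edgeR, with 529 and 713 at an unadjusted p under 0.05. The median 95% interval reached a factor of 2.93 either way for genes with a mean RPKM under 1, and 1.45 from 1 to 10, 1.27 from 10 to 100 and 1.28 above 100. The count of 0 did not hold without control iPSC 7, a fit in which control iPSC 3 was the only control line. Differences there are those of the PC lines from control iPSC 3 alone. That line stood apart from the others in the fibroblast and interferon lists, with medians of -0.61 and -0.64 from the mean of the 4 iPSC lines. Such calls cannot tell a group difference from a trait of control iPSC 3.

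The leading genes by size of change did not pass the test with all lines. Trpm1, a cation channel of melanocytes and retina (chromosome 7, 64153835 to 64269772), stood at 2.17 and 2.12 in the PC lines against 5.31 and 3.85 in the control lines, a log2 difference of -1.12 (SE 0.22). Aldh3a1, an aldehyde dehydrogenase (chromosome 11, 61208510 to 61218418), stood at 1.13 and 1.00 against 0.482 and 0.371, a difference of 1.29 (SE 0.22). Its level in MEF was 728 and the iPSC lines were kept on fibroblast feeders. Other leading genes high in MEF were lower in PC iPSC, Mgp (1663 in MEF) at -0.97 and Col10a1 (463.3 in MEF) at -1.09. RNA with the profile of the MEF library would carry these genes too. A trace of feeder RNA with another profile cannot be told apart from a difference in the lines' own Aldh3a1. Higher values in PC iPSC were also measured for the antiviral gene Rsad2 (1.34, SE 0.51) and the zinc finger gene Zic2 (1.40, SE 0.42). Lower values were measured for Chga, the neuroendocrine protein chromogranin A (-0.98, SE 0.23), and Ntn1, the axon guidance protein netrin 1 (-0.97, SE 0.23). The edgeR adjusted p was 0.963 for Trpm1, Aldh3a1, Rsad2, Zic2, Chga and Ntn1, and also for Mgp and Col10a1. Without control iPSC 7, control iPSC 3 was the only control line. In that fit the differences were 2.54 for Rsad2, -1.33 for Trpm1, -1.20 for Chga and -1.27 for Ntn1. Among genes with no overlap of groups and an RPKM of at least 1 in both PC lines, Rhox4g had the largest difference, 1.73 (SE 0.65). It belongs to a family of near-identical copies on chromosome X, so its counts are uncertain. Mirg, a noncoding RNA of the imprinted Dlk1-Dio3 region (chromosome 12, 109734981 to 109749458), stood at 0.741 and 0.868 in the PC lines against 0.386 and 0.373, a difference of 1.06 (SE 0.51), while the neighbouring noncoding genes Meg3 and Rian differed by 0.06 (SE 0.18) and 0.19 (SE 0.25).

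As groups, fibroblast and interferon genes were higher in PC iPSC relative to other genes at the preset correlation, and genes of oxidative phosphorylation and of the cell cycle were lower. With an estimated correlation none of the 8 called lists was called (adjusted p = 0.761 for 7 lists and adjusted p = 0.791 for the ribosomal list, with an estimated correlation). Of 40 fibroblast and mesenchymal genes, 38 had a positive difference (median log2 difference 0.37, camera adjusted p = 2.22e-07), among them the matrix genes Tgfbi (0.83), Col6a3 (0.69) and Lum (0.62). Of 29 interferon and antigen presentation genes, 28 were positive (median 0.46, adjusted p = 2.22e-07), led by Rsad2 and by Ifit1 at 0.86 and Oasl2 at 0.81. Of 33 germline genes, 26 were positive (median 0.42, adjusted p = 0.00468), including Rhox6 and Rhox9, whose family copies make counts uncertain. Of 79 nuclear-encoded oxidative phosphorylation genes, 17 were positive (median -0.10, adjusted p = 1.52e-06), with Cox7b at -0.41. Of 32 cell cycle genes, 5 were positive (median -0.15, adjusted p = 0.0012), with Mcm5 at -0.36. DNA and histone modifiers (7 of 37 positive, adjusted p = 0.0202), naive and general pluripotency genes (10 of 36, adjusted p = 0.0238) and ribosomal protein genes (6 of 35, adjusted p = 0.0291) were lower as groups, with medians of -0.11, -0.13 and -0.08. In each of these 8 lists 0 members were called, both over all genes and adjusted over the list alone. Fry gave adjusted p values from 0.644 to 0.756 for the 8 lists.

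Single lines or the scale decided most of these list calls. The fibroblast list stood at -0.61 in control iPSC 3, measured as the median from the mean of the 4 lines, and at 0.20 in control iPSC 7, 0.31 in PC iPSC 5 and 0.12 in PC iPSC 13. The interferon list went with it, at -0.64, 0.20, 0.34 and 0.21. Without control iPSC 3 the medians of the fibroblast and interferon lists were 0.02 and 0.04, and neither was called. The germline list stood at 0.54 in PC iPSC 5 and between -0.19 and 0.00 in the other 3 lines, and its median without PC iPSC 5 was -0.06. Its call also ended without control iPSC 3 (median 0.26). Leaving out PC iPSC 5 or control iPSC 3 ended the calls of the cell cycle list (medians -0.07 and -0.10), of the DNA and histone modifiers (-0.06 and -0.03) and of the naive pluripotency list (-0.05 and -0.03). The ribosomal median was 0.05 without PC iPSC 5, and its call ended without control iPSC 7 too (-0.04). With all lines kept, quantile normalization ended the calls of the ribosomal (median -0.01), naive pluripotency (-0.11) and DNA and histone modifier (-0.11) lists. The ribosomal call also ended with a pseudocount of 0.1 and with a mean RPKM of at least 5, and the naive pluripotency call without a filter and without chromosome 11, though these medians stayed close to those given (-0.07 and -0.07, and -0.12 and -0.11). The oxidative phosphorylation list was called under each alternative tried for lists but the estimated correlation, with medians from -0.16 to -0.08. Lists were not tested with DESeq2 or in the fit of the 4 iPSC libraries alone.

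**Figure D1:**
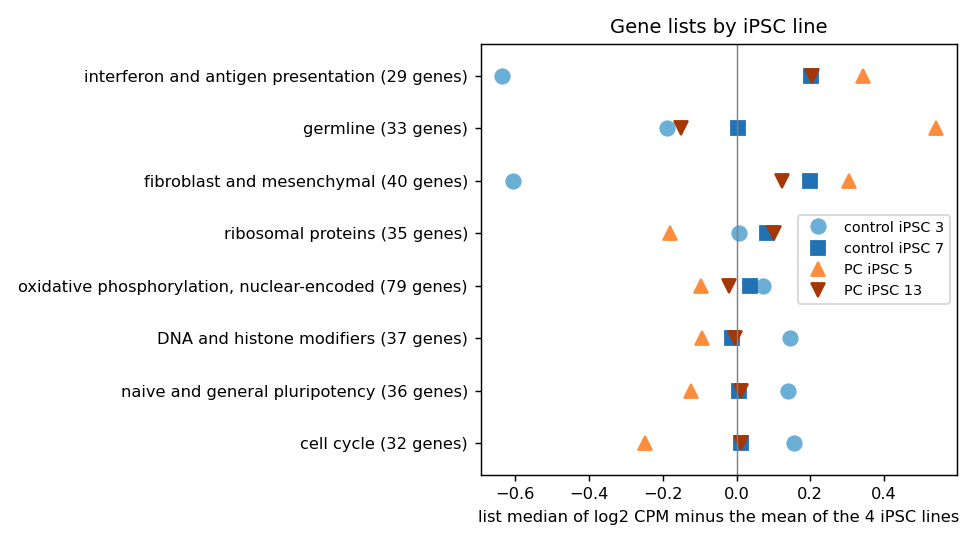
Median log2 CPM of each gene list in each iPSC line, minus the mean of the 4 lines, for the 8 lists called between PC and control iPSC; each point is 1 line. Control iPSC 3 lies apart at -0.61 for the fibroblast list and -0.64 for the interferon list, and PC iPSC 5 lies apart at 0.54 for the germline list.

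The remaining 23 lists were not called between PC and control iPSC with all lines and at the default settings. Of these, 7 were called under some alternative. Leaving out a single line called the 2-cell-like list lower without control iPSC 3 (median -0.25) and higher without control iPSC 7 (0.72) or PC iPSC 5 (0.52). It also called the trophoblast (0.37) and epithelial (0.34) lists higher without PC iPSC 13, the endoplasmic reticulum stress list lower without PC iPSC 5 (-0.11) and the X inactivation and Y-linked list lower without control iPSC 3 (-0.25). With a mean RPKM of at least 5 the imprinted (0.17) and p53 (0.16) lists were called higher. The carnitine shuttle and fatty acid oxidation list had 26 of 43 members positive (median 0.06, adjusted p = 0.271). The carnitine importer Slc22a5 differed by 0.76 (SE 0.41) and Acadvl, which oxidises long-chain acyl-CoA, by 0.44 (SE 0.23). Both lie on chromosome 11 and both differences came from PC iPSC 5, where Slc22a5 stood at 8.06 against 3.11 in PC iPSC 13 and 3.65 and 2.81 in the control lines, and Acadvl at 44.7 against 26.4, 24.1 and 27.4. The protein kinase C family had 9 of 14 positive (median 0.16, adjusted p = 0.268). Adjusted p was 0.271 for fatty acid and triglyceride synthesis, 0.162 for cholesterol synthesis, 0.58 for glycolysis and lactate, 0.268 for the tricarboxylic acid cycle, 0.139 for imprinted genes, 0.137 for p53 targets and senescence and 0.137 for endoplasmic reticulum stress. Among lineage lists it was 0.268 for primed pluripotency, 0.308 for 2-cell-like genes, 0.286 for epithelial, 0.839 for ectoderm, 0.908 for mesoderm, 0.92 for endoderm, 0.17 for trophoblast, 0.908 for macrophage and 0.195 for endothelial genes. It was 0.92 for hypoxia, 0.275 for inflammation, 0.565 for X inactivation and Y-linked genes, 0.531 for LIF, BMP, FGF and WNT signalling and 0.831 for matrix remodelling. The list of 4 reprogramming factor genes was too short to test, and its members differed by -0.26 (Klf4), 0.20 (Myc), -0.17 (Pou5f1) and -0.10 (Sox2).

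Genes of chromosome 11 were higher in PC iPSC 5 and in ESC than in the other iPSC lines. Over 1019 genes of chromosome 11, the median log2 difference from the mean of the other iPSC lines was 0.40 in PC iPSC 5, or 1.32-fold, and 93.1% of these genes were higher. Medians of the other autosomes in this line ran from -0.08 to -0.01. In ESC the chromosome 11 median was 0.40, or 1.32-fold, with 79.4% of genes higher and other autosomes from -0.15 to 0.02. In control iPSC 3 and 7 and PC iPSC 13 it was 0.01, -0.01 and 0.01. With genes of chromosome 11 left out, a fit chosen after seeing the data, edgeR called 0 genes between PC and control iPSC and 1739 between iPSC and ESC.

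**Figure D2:**
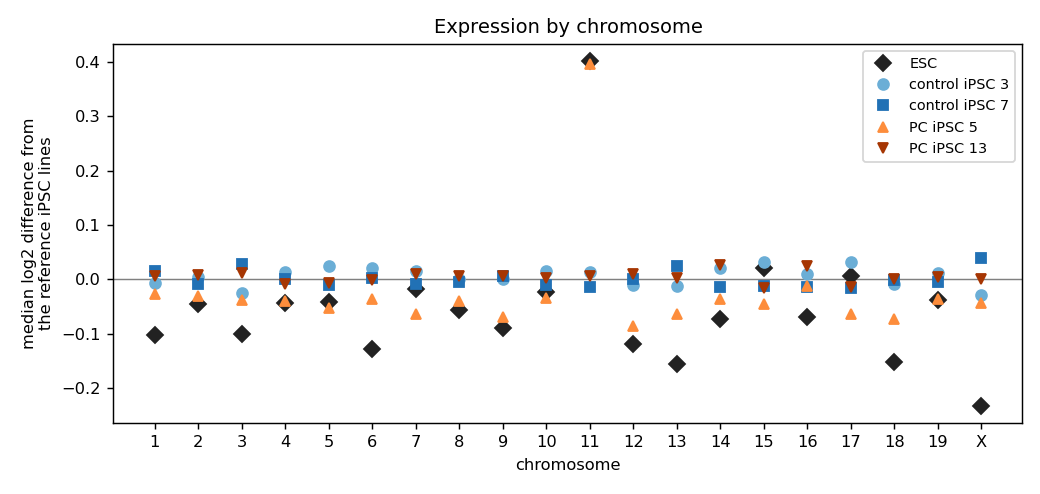
Median log2 difference of genes from the mean of the reference iPSC lines, by chromosome, for ESC and the 4 iPSC lines; the reference is control iPSC 3, control iPSC 7 and PC iPSC 13, without the library itself, and MEF and chromosome Y are not drawn. PC iPSC 5 and ESC stand at 0.40 on chromosome 11.

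PC and control iPSC lay at like distances from ESC. Pearson's r across 13943 genes with the ESC library was 0.964 and 0.953 for PC iPSC 5 and 13 and 0.962 and 0.954 for control iPSC 3 and 7. The mean was 0.958 in each group, and the difference of 0.000645 was smaller than the SD within either group (0.00747 and 0.00571, exact permutation p = 1, two-sided). Genes are not independent replicates, and 0.333 is the smallest p that 2 lines against 2 allow. These values include the genes of chromosome 11, which were higher in both PC iPSC 5 and ESC, and they were not computed without them. The root mean square log2 difference from ESC was 0.575 in PC iPSC and 0.578 in control iPSC. By the same measure the closest iPSC lines were control iPSC 7 and PC iPSC 13, of opposite groups, at 0.180. The 2 control lines differed by 0.280 and the 2 PC lines by 0.317. The remaining pairs across groups lay between 0.283 and 0.383.

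Against ESC, the iPSC lines had more Klf4 and Myc RNA and less of the epithelial genes Epcam and Esrp1 and of the Nodal antagonist Lefty1. Klf4, a reprogramming factor of naive pluripotency (chromosome 4, 55527137 to 55532475), stood at 88.6 ± 12 in iPSC (SD, n = 4) against 21.4 in ESC, a log2 fold change of 2.00 (SE 0.22, adjusted p = 0.00882). Myc, a growth-promoting transcription factor (chromosome 15, 61985341 to 61990361), stood at 38.0 ± 14.1 against 2.82, a change of 3.71 (SE 0.56, adjusted p = 0.0173). The reprogramming method is not given, and reads per gene cannot tell introduced factors from the cells' own Klf4 and Myc. Epcam, an epithelial adhesion molecule (chromosome 17, 87635979 to 87651127), stood at 31 ± 2.63 against 122.8, a change of -2.03 (SE 0.14, adjusted p = 0.00305). Esrp1, an epithelial splicing regulator (chromosome 4, 11331933 to 11386783), changed by -3.80 (SE 0.26, adjusted p = 0.00305), and Lefty1 (chromosome 1, 180935022 to 180938401) by -5.32 (SE 0.52, adjusted p = 0.00661). Pou5f1, Sox2 and Nanog differed by -0.36 (SE 0.19), -0.43 (SE 0.16) and 0.34 (SE 0.16), with adjusted p values of 0.261, 0.121 and 0.209.

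Of 16435 genes, 1713 were called between iPSC and ESC, 774 higher and 939 lower in iPSC, and 579 and 564 of these by at least 2-fold. The 4 iPSC lines lay on one side of ESC for 66.2% of genes, where chance gives 40%. The leading higher genes had no read in ESC. They were at least 57.8-fold higher for Dpt, a dermal matrix protein, 50.2 for Tdpoz4, 38.3 for Trim43b, 22.3 for Map3k7cl, 19.6 for Obox3, 18.2 for Ptpn22, 16.4 for Alppl2, 14.6 for Pik3r6 and 12.2 for Upk1b. Among the leading lower genes, Serpinb5 was at least 9.43-fold lower and Tmprss11f at least 8.13-fold lower, with no read in iPSC. The metallothionein Mt4 changed by -7.09 (SE 0.84), the vesicle protein gene Nrsn1 by -5.40 (SE 0.59) and Nnt, the mitochondrial nicotinamide nucleotide transhydrogenase, by -5.49 (SE 0.81).

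The number of genes called depended on the lines and the scale used. Without control iPSC 3 it was 2873 and without control iPSC 7 it was 2734, limma called 122 without and 328 with a trend, and DESeq2 called 2367. Calls were higher in iPSC for 45.2% of genes as given above, 33.7% (141 of 418) after quantile normalization, 55.3% by DESeq2 and 64.1% (100 of 156) with a pseudocount of 0.1. The calls of Myc and Lefty1 ended on the log2 RPKM scale with limma without a trend, where the folds were 3.28 and -5.08 and adjusted p was 0.0566 and 0.0518. Over their alternatives the adjusted p ran from 1.13e-23 to 0.0566 for Myc and from 2.34e-52 to 0.0579 for Lefty1. Among the leading genes above, the calls of Dpt, Tdpoz4, Trim43b, Map3k7cl, Obox3, Alppl2 and Upk1b ended with a pseudocount of 0.1, after quantile normalization and with limma with or without a trend. That of Pik3r6 ended under the last 3 of these, that of Serpinb5 with limma and that of Nnt with a pseudocount of 0.1, where its fold was -4.76. Without PC iPSC 13 the calls of Obox3 and Tmprss11f ended.

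Camera called 7 lists between iPSC and ESC at the preset correlation, with 2-cell-like and fibroblast lists higher and glycolysis, epithelial and hypoxia lists lower in iPSC. None of the 7 calls held with an estimated correlation (adjusted p = 0.505 for glycolysis and adjusted p = 0.814 for the other 6 lists, with an estimated correlation). As between PC and control iPSC, this loss does not show that the lists were unchanged. Of 28 genes of the 2-cell-like state, a rare state of ESC that resembles the early embryo, 16 rose, 1 fell and 11 did not pass, with 27 called when adjusted over the list alone (median log2 fold change 3.10, camera adjusted p = 2e-08). Zfp352 rose by 6.20 (SE 1.09) and Tdpoz3, with 1 to 3 reads in ESC, by a ratio of 80.8 (95% counting interval 22.4 to 667). The Tdpoz, Obox, Zscan4 and Usp17l families are near-identical copies whose counts are uncertain. Of 40 fibroblast genes, 13 rose and 27 did not pass, with 22 adjusted over the list alone (median 1.14, adjusted p = 2e-08), among them Lum at 2.65 (SE 0.44) and Postn at 2.39 (SE 0.57), while Col1a1 at 1.66 (SE 0.43) did not pass. Of 9 genes of X inactivation and the Y chromosome, 4 rose, with 6 adjusted over the list alone (adjusted p = 0.000453). Y-linked Eif2s3y stood at 26.8 ± 6.20 in iPSC against 3.48 in ESC.

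Of 28 glycolysis and lactate genes, 15 fell and 13 did not pass, with 19 adjusted over the list alone (median -0.78, adjusted p = 2.05e-10). The aldolase Aldoc (chromosome 11, 78323073 to 78327781) fell by 2.43 (SE 0.21) and the lactate exporter Slc16a3 (chromosome 11, 120948484 to 120959000) fell by 2.15 (SE 0.15), both on the chromosome whose genes were higher in ESC by a median of 0.40. The lactate dehydrogenase Ldhb and the glucose transporter Slc2a1 changed by -2.39 (SE 0.47) and -1.61 (SE 0.20). Of 18 epithelial genes, 9 fell, with 12 adjusted over the list alone (median -1.55, adjusted p = 1.9e-07), including Cldn4 and Cldn7 at -2.05 and -2.24. Of 20 hypoxia genes, 9 fell, with 12 adjusted over the list alone (median -0.66, adjusted p = 2.65e-05), including Egln3 at -2.28 and Ndrg1 at -1.63. Of 21 ectoderm and neural genes, 4 fell, with 5 adjusted over the list alone (median -0.73, adjusted p = 0.00124), including Map2 at -1.92. As above, glycolysis had an adjusted p = 0.505 with an estimated correlation, and the other 3 lists adjusted p = 0.814. By fry, adjusted p was 0.00428 for glycolysis and 0.066 or more for the others.

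The other 24 lists were not called by camera between iPSC and ESC, though alternatives called 7 of them. Of 36 naive and general pluripotency genes, 5 rose and 5 fell (12 adjusted over the list alone, adjusted p = 0.8). Zfp42 rose by 1.24 (SE 0.18) and Tdh by 1.97 (SE 0.23), and Klf2 fell by 1.81 (SE 0.15). The call of Zfp42 ended with limma without a trend (1.26, limma adjusted p = 0.0507). Of 45 imprinted genes, 3 rose and 7 fell (adjusted p = 0.225), with Dio3 at 3.11 (SE 0.58) and Dlk1 at -2.12 (SE 0.31). Of 43 carnitine and fatty acid oxidation genes, 4 rose and 2 fell (adjusted p = 0.736), with the thiolase Acaa2 at 1.07 (SE 0.16). Of 79 oxidative phosphorylation genes 0 were called by edgeR over all genes and 0 adjusted over the list alone (adjusted p = 0.308). Of 11 macrophage and blood genes, 2 fell (adjusted p = 0.131), Cd68 at -2.38 (SE 0.19) and Lyz2 at -1.41 (SE 0.20). Of 22 matrix remodelling and adhesion genes 1 rose, Cd44 at 1.60 (SE 0.36), and the list (median 0.47, adjusted p = 0.061) was called higher under 6 of 13 alternatives, where its adjusted p ran from 0.013 to 0.814. The ribosomal list was called lower under 5 alternatives, with medians from -0.22 to -0.11, and the interferon list under 3, from -0.61 without control iPSC 7 to -0.38. The macrophage list was called lower without control iPSC 3 (-1.16) and the primed pluripotency list higher with a mean RPKM of at least 5 (0.94).

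Taken by group, edgeR called 855 genes between PC iPSC and ESC, 426 higher and 429 lower, and 1156 between control iPSC and ESC, 529 higher and 627 lower. The difference between these is the PC against control comparison, in which 0 genes were called by edgeR (385 at an unadjusted p under 0.05). After quantile normalization the calls were 27 higher of 105 (25.7%, against 49.8% above) and 44 higher of 160 (27.5%, against 45.8%). DESeq2 called 1776 and 2070 genes. Leaving out 1 line gave 260 to 2591 calls for PC iPSC, lowest without PC iPSC 13 and highest without control iPSC 7. For control iPSC it gave 1802 to 2301.

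Against MEF, 35 of 36 naive and general pluripotency genes rose in the iPSC lines, though Pou5f1 and Sox2 rose by 1.64 and 0.90 only. Dppa5a, an RNA-binding protein of pluripotent cells (chromosome 9, 78367052 to 78368199), stood at 2654 ± 358.9 in iPSC (SD, n = 4) with no read in MEF, at least 16000-fold higher. Esrrb, an orphan nuclear receptor (chromosome 12, 86361117 to 86521628), was at least 4430-fold higher and Zfp42 at least 2760-fold higher. Nanog had 3 reads in MEF, a ratio of 8580 (95% counting interval 2940 to 41600). Dcn, the matrix proteoglycan decorin (chromosome 10, 97479500 to 97518163), fell by 7.40 (SE 0.16) and the eye and matrix protein Myoc, with no read in iPSC, was at least 3820-fold lower.

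Of 16435 genes, 11185 were called between iPSC and MEF, 5993 higher and 5192 lower in iPSC, and 4683 and 3964 by at least 2-fold. The median of all genes was 0.16 log2 units above 0, and it was 0.05 after quantile normalization, so the split between higher and lower calls moves with the scaling. Other leading higher genes, at least 972-fold each with no read in MEF, were Tdgf1, Rhox5, Gldc, Calcoco2, Trap1a, Mcf2 and Lin28a. Other leading lower genes included Slurp1 and Gdf10, at least 2600-fold and 1430-fold lower, Clec3b at -12.82 (SE 0.33) and Vsnl1, with a ratio of 5210 (95% counting interval 1440 to 43000).

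Of the list of reprogramming factor genes, Pou5f1 and Sox2 rose by 1.64 (SE 0.22, adjusted p = 0.000675) and 0.90 (SE 0.17, adjusted p = 0.00321) in iPSC against MEF, and Myc fell by 2.00 (SE 0.37, adjusted p = 0.00281). Klf4 differed by -0.46 (SE 0.18, adjusted p = 0.0596) and did not pass, though it passed after median-of-ratios scaling (-0.55) and quantile normalization (-0.75). In the MEF library Pou5f1 stood at 157.7, Sox2 at 88.2, Klf4 at 123.5 and Myc at 153.9, which are 32.6%, 54.5%, 139% and 405% of the iPSC means. The other 33 pluripotency genes had a median of 0.0596% of the iPSC mean in MEF.

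**Figure D3:**
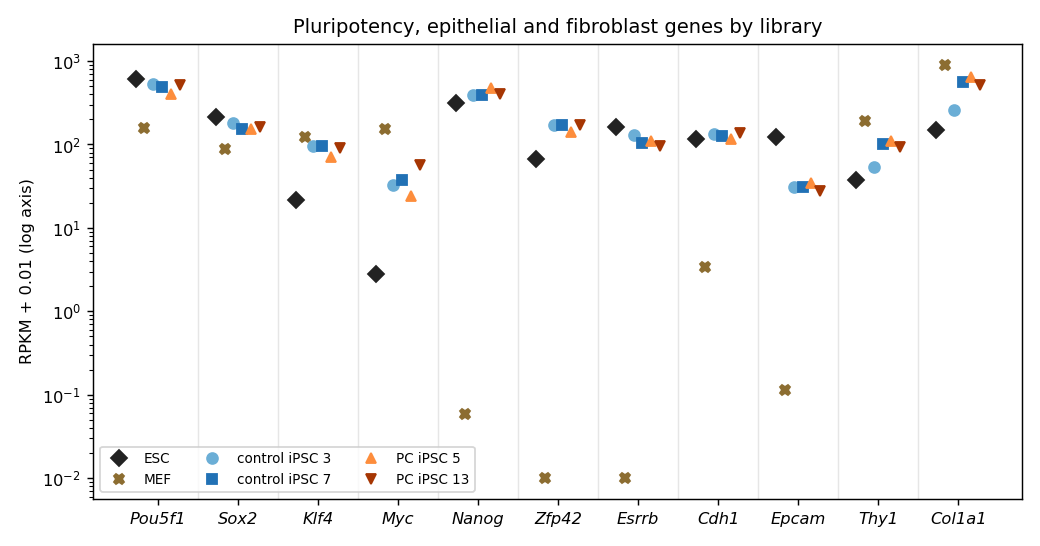
RPKM of 11 pluripotency, epithelial and fibroblast genes in each of the 6 libraries, on a log axis after adding 0.01, so that a gene without reads is drawn at 0.01; each point is 1 library. In MEF, Pou5f1, Sox2, Klf4 and Myc lie between 88.2 and 157.7. Zfp42 and Esrrb, without reads in MEF, lie at 0.01, and Nanog, at an RPKM of 0.0482, lies above them.

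Of the 31 lists, 13 were called between iPSC and MEF, 10 up and 3 down. None of the 13 calls held with an estimated correlation (adjusted p = 0.601 with an estimated correlation for each). This included the naive pluripotency list, in which 35 of 36 genes rose. The loss of a call in that version therefore does not show that a list was unchanged. Of 36 naive pluripotency genes 35 rose (median 8.42, or 7.83 with genes lacking reads at their bound, adjusted p = 5.11e-19), and of 33 germline genes 30 rose (8.37, or 4.88 at bounds). Of 28 genes of the 2-cell-like list 27 rose (10.29, or 5.73 at bounds). Of 32 cell cycle genes 29 rose and 1 fell, with Ccnb1 at 5.62 (SE 0.32), and 35 of 35 ribosomal protein genes and 70 of 79 oxidative phosphorylation genes rose. Of 28 glycolysis genes 17 rose and 4 fell, of 22 tricarboxylic acid cycle genes 16 rose and 1 fell, of 18 epithelial genes 13 rose and 1 fell, and of 37 DNA and histone modifiers 24 rose and 5 fell. Of 40 fibroblast genes 33 fell and 2 rose (median -2.00, adjusted p = 1.05e-09), of 11 macrophage and blood genes 10 fell and 1 rose, and of 32 LIF, BMP, FGF and WNT signalling genes 18 fell and 9 rose. Adjusted over the list alone, 36 naive pluripotency, 30 cell cycle, 71 oxidative phosphorylation and 35 fibroblast genes were called. The glycolysis call ended with a pseudocount of 0.1 (median 1.00, against 1.03) and the tricarboxylic acid cycle call with a mean RPKM of at least 5 (0.54, against 0.77). The imprinted, mesoderm, endoderm and matrix remodelling lists, not called here, were called lower with a mean RPKM of at least 5 (-1.02, -3.46, -4.69 and -1.06), and the matrix remodelling list also without control iPSC 7 (-0.71). Cpt1a fell by 0.56 (SE 0.14) and Slc25a20 rose by 1.26 (SE 0.20), while the carnitine list as a whole was not called (17 rose and 11 fell of 43, adjusted p = 0.773).

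ESC and MEF, 1 library each, differed by at least 1 log2 unit of RPKM + 1 for 6716 of 13943 genes, 3393 higher and 3323 lower in ESC. This difference has no replicate check. Among 10000 random lists of like expression, the median of the naive pluripotency list (4.42) lay at percentile 100, that of cell cycle genes (3.64) and of ribosomal protein genes (1.59) at 100, and those of the fibroblast (-3.11) and macrophage (-3.79) lists at 0. The 2-cell-like list (0.54) lay at 72.2 and the carnitine list (0.06) at 43.7. Nanog stood at 316.1 in ESC and 0.0482 in MEF, and Col1a1 at 149 and 904.2.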

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

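Limma with a trend and the fit without chromosome 11 were chosen after seeing the data. Of the counts under alternatives, 73 stayed within 1.5 times the value reported and 35 moved. Named genes stayed on the same side of the threshold in 597 of their alternatives for PC against control iPSC (12 gained a call), in 426 against ESC (16 gained and 51 lost a call) and in 479 against MEF (19 gained and 6 lost). Among these the sign changed in 23, 6 and 0. Single lists stayed on the same side in 363, 373 and 379, and the sign of the median changed in 21, 23 and 22 of them. The macrophage and blood list, for example, ran from -0.318 to 0.691 between PC and control iPSC. Against MEF, the mesoderm median of 0.303 was -3.456 with a mean RPKM of at least 5, where the list was called lower.

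Between PC and control iPSC, leaving out 1 line gave 0 to 309 genes. Against ESC, all iPSC lines gave 156 genes with a pseudocount of 0.1, 953 with a mean RPKM of at least 5, 418 after quantile normalization, 122 with limma without a trend, 328 with a trend, and 1781 to 2873 without 1 line. PC iPSC gave 3, 366, 105, 6 and 13 under those settings, 1309 without a filter, 1776 by DESeq2 and 260 to 2591 without 1 line. Control iPSC gave 3, 651, 160, 5 and 9, 2070 by DESeq2, and 1802 to 2301 without 1 line. Against MEF a mean RPKM of at least 5 gave 6558 genes, with 9044 genes tested, so fewer could be called. The cause of the other shifts was not tested. Called lists numbered 5 after quantile normalization and 4 to 10 without 1 line for PC against control iPSC, and 0 with an estimated correlation in all 3 comparisons. Between PC and control iPSC, 3 lists that were called with all lines or without a line had opposite signs in the pair of fits. The 2-cell-like median of 0.146 was -0.253 without control iPSC 3 and ran from -0.346 to 0.722 over the lines left out. The germline median was -0.059 and the ribosomal median 0.051 without PC iPSC 5, and they reached 0.606 and -0.215 without PC iPSC 13. The cause was not tested. Leaving out a line leaves 1 line in its group, which is assumed to vary like the others. The difference in similarity to ESC ran from -0.00052 to 0.00235 under its 4 alternatives, each within the spread between lines of the value reported, and the ESC against MEF count ran from 6566 to 7887. No paired analysis was possible because the groups share no replicate numbers. For genes under 1 RPKM the median 95% interval between PC and control iPSC reached a factor of 2.93.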

Other observations

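The trophoblast, mesoderm and germline lists were not called by camera between iPSC and ESC (adjusted p = 0.0744, 0.632 and 0.632). Of 16 trophoblast genes 2 rose and 3 fell, of 23 mesoderm genes 3 rose and 1 fell, and of 33 germline genes 4 rose and 2 fell, where edgeR called 10.4% of all genes. With a mean RPKM of at least 5 the trophoblast list was called lower (median -1.09) and the mesoderm list higher (1.21), and without PC iPSC 5 the trophoblast list was called lower (-0.57). The trophoblast and epithelial receptor Fgfr2 fell by 2.90 on the log2 scale (SE 0.24, edgeR adjusted p = 0.00611) and the trophoblast factor Tfap2c fell by 2.37 (SE 0.33), while the signalling protein Bmp4 rose by 2.43 (SE 0.27) and the mesoderm factor Hand2 by 2.25 (SE 0.46). The meiotic gene Sycp1 rose by 2.67 (SE 0.29) and Prdm1, a regulator of germ cell precursors, fell by 2.58 (SE 0.29). Nnt, which is deleted in part in some laboratory mouse strains, stood at 5.40 RPKM in ESC and 6.92 in MEF and between 0.0141 and 0.473 in the 4 iPSC lines. The ESC library is titled B6, also a short name of a mouse strain, and no label gives a strain for the iPSC or MEF, so differences between iPSC and ESC include any between strains or lines. Xist (chromosome X, 103460373 to 103483233, a long noncoding RNA) stood at 2.54 in ESC, 5.79 ± 1.27 in iPSC (SD, n = 4) and 0.00798 in MEF.

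The tests in the next paragraphs were chosen only after the result was seen, except that of GC content.

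Genes of chromosome 11 were 1.32-fold higher in PC iPSC 5. Palmitoylcarnitine acting on every line of its group would raise them in PC iPSC 13 too, where the median difference from the control lines was 0.006. Genes of other chromosomes with the same GC content did not share the shift, and the difference that remained was 0.429. An extra copy of chromosome 11 in cells of PC iPSC 5 may account for the pattern. The lowest of the 10 Mb windows with at least 20 genes stood at 0.256, above a bound of 0.1. That bound was set after the chromosome median of 0.396 was seen, so passing it decides little. ESC had a like median of 0.401, with 0.189 in the same window, and no explanation was tested for it.

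Pou5f1, Sox2, Klf4 and Myc were high in the MEF library. Pluripotent cells or their RNA in that library would bring the other pluripotency genes, and these had a median of 0.0596% of the iPSC mean, with 14 of 33 lacking a read. Reprogramming factors introduced into the fibroblasts may explain the 4 genes, the lowest of which stood at 32.6% of the iPSC mean. They cannot be told apart from expression of the cells' own genes, because reads per gene carry no vector sequence.

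The fibroblast and interferon lists were called higher in PC than in control iPSC at the preset correlation, with adjusted p = 0.761 for each with an estimated correlation. Without control iPSC 3 the medians were 0.021 and 0.04, which only restates the low values of that line, so a cause in this line alone cannot be told apart from a difference between the groups with 2 lines in each. Feeder RNA with the profile of the MEF library could cover at most 28.0% of the median fibroblast gene's difference. Its share is bounded there at 1.56% by the third lowest of 32 list genes with at least 50 RPKM in MEF. That share is too high for other genes, as Dcn stood at 0.631% and Pdgfra at 1.27% of MEF in the PC lines. Myoc, at 201.2 RPKM in MEF, had no read in any iPSC line. RNA with this profile could therefore cover less than 28.0%. The bound was first taken over all 4 iPSC lines, which gave 23.0%, and after that value was seen it was taken over the PC lines, because a difference in feeder share cannot exceed theirs; the floor and the rank were also set with the data in view. Feeder cells in another state, which were not sequenced here, and an effect of palmitoylcarnitine that control iPSC 7 happens to mask stay open and untested.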
